A study of Homo sapiens with 12 samples.

How the data were processed

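RNA sequencing was compared between 4 groups of 3 libraries from PANC-1, an established human cell line from a pancreatic carcinoma, after 24 h with vehicle (DMSO), 30 nM chaetocin, 90 nM MLN8237, or both compounds. The combination samples carry a code in their labels that differs from MLN8237 by a digit and was read as MLN8237. Per the labels' protocols, RNA extraction included a DNA digestion on the column. CASAVA 1.9, TopHat 12.0.6, HTSeq and hg19 are named in the submitters' processing notes, without roles or order. The TopHat version is printed as it stands there. Whether reads were counted by strand is not given in the sources used here.

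The authors deposited a table of 57773 Ensembl genes that holds, per the file headers, a raw count and an RPKM value per gene and library, with gene positions and a gene length. The counts are whole numbers that sum to 49439795 to 63747510 per library. The deposited RPKM values, which by their name are scaled to gene length and library total, were not used for testing. They served only to recover the total that RPKM was scaled to, and the percentage of that total lying outside the summed gene counts was computed per library. RPKM values over genes silent in vehicle were computed instead from the counts and summed gene counts. What the deposited total comprises is not given in the sources used here. Of the gene lengths, 33.7% were multiples of 3, so lengths are not coding lengths alone. Coordinates are those of the authors' table, read as hg19. A newer human annotation was used only to give each tested gene a type by Ensembl identifier, which matched 95.4% of tested genes.

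Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes passing the default expression filter by group (22831 genes) were scaled by TMM and fitted in a model with 4 group means over all 12 libraries. Contrasts were tested with the robust quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg, with changes called at an adjusted p under 0.05. The common biological coefficient of variation was 0.155. The contrasts were each treatment against vehicle, the combination against each compound, and the interaction, which is the log2 change with both compounds minus the sum of the log2 changes with each. CPM values are TMM-scaled, given as mean ± SD (n = 3), and fold changes carry the standard error of the fit. Against a group with no counts, a fold is a lower bound against a floor of 3 counts over the group. Such floors cover counting error only.

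Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. Camera asks whether list members move relative to other genes. Of 31 lists, 30 had at least 5 measured genes and were tested. They covered H3K9 methyltransferases and heterochromatin, Aurora kinases and partners, mitosis and G2/M, G1/S and DNA replication, DNA repair, histone genes and p53 targets. Stress lists covered oxidative stress and NRF2 targets, metallothioneins, the unfolded protein and integrated stress response, heat shock and hypoxia. Others were cholesterol and fatty acid synthesis, apoptosis regulators, NF-kB and secretory genes, interferon-stimulated genes and immediate early genes. The last were epithelial genes, mesenchymal genes, Polycomb and DNA methylation enzymes, zinc finger ZNF genes, germline genes, autophagy and lysosome, cytosolic ribosomal proteins and mitochondria-encoded genes. Markers of immune, endothelial, acinar, endocrine and ductal cells completed them, and 1 list is not reported here. The ribosomal protein list was taken by symbol and holds pseudogenes. Some genes belong to more than 1 list, such as EGR1, ATF3, SLC7A11, AURKA and KRT19.

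Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Genes were named by this rule: for each comparison with vehicle, the 10 largest changes each way among genes that passed, had a mean of at least 5 CPM and did not overlap between the groups, of which not every gene is printed. For the combination against each compound and for the interaction it was 5 each way. Where no gene passed, the 3 smallest p each way were taken. Up to 4 members of each list with the smallest p were added. AURKA, SUV39H1, SUV39H2, EHMT2 and TXNRD1, whose products the compounds are known to inhibit, were followed in every comparison. Chance leaves 10% of genes without overlap between 3 libraries and 3 others.

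Alternatives were RLE scaling, no filter (at least 1 count in any library), a stricter filter (at least 1 CPM in at least 6 libraries), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, an added absolute log2 fold change of at least 1, and each library left out in turn. For lists they were an estimated correlation and fry. Left-out libraries outside the groups compared, the omission of the 3 treated libraries numbered 3, offsets removing each library's trend with gene length, and both filters for gene lists were added after seeing the data. So were, for lists with members near 0 in vehicle, counts over members whose vehicle mean reached 0.178 CPM, which picks members by a group that is compared, and the percentile of a list's median among 10000 random lists matched on mean log2 CPM. The tests were checked on simulated counts for chaetocin against vehicle, with 200 of 22256 genes changed. At 1.5-fold, 2-fold and 4-fold edgeR recovered 32.8%, 86.6% and 98.5%, with 4 false calls. DESeq2 recovered 49.3%, 91% and 100%, with 26, and limma-voom 31.3%, 88.1% and 98.5%, with 4. Recovery by expression or under 1 CPM is unknown. A library's position was its projection, on log2 CPM, on the axis from the vehicle mean (0) to the chaetocin mean (1) over 6793 genes changed with chaetocin in a fit without the MLN8237 libraries, a measure chosen after seeing the data. Measures of whole libraries were compared by two-sided exact permutation tests. For 3 libraries against 3, such a test has 10 splits and cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.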

Results

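Gene expression was measured by RNA sequencing in PANC-1 pancreatic carcinoma cells after 24 h in 4 conditions, with 3 libraries each. Chaetocin is a fungal compound known as an inhibitor of the histone H3K9 methyltransferase SUV39H1 and of thioredoxin reductase. MLN8237 (alisertib) is an inhibitor of the mitotic kinase Aurora A. Summed gene counts were 49439795, 56370345 and 57539126 in the vehicle libraries and 56213168, 63747510 and 57284302 with chaetocin. They were 55969727, 50004060 and 50678374 with MLN8237, and 58671039, 55189074 and 55033617 with both. Of 57773 genes in the table, 16155 had no count in any library and 22831 were tested. The median standard error of a log2 fold change between groups was 0.179 for chaetocin against vehicle. No pair of libraries within a group agreed within sampling noise (chi-square per gene 5.739 to 126.1). The labels do not say whether libraries came from separate cultures, so p-values measure the spread among these libraries, which may be technical.

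The leading principal component held 59.9% of the variance and placed the 6 libraries with chaetocin (37.3 to 95.3) apart from the 6 without it (-71.1 to -52.2). Combination replicate 2, at 50.8, lay near the chaetocin libraries, while combination replicates 1 and 3 lay at 95.3 and 89.0. The next component held 14.6% and set apart the 3 treated libraries numbered 3. MLN8237 replicate 3 lay at 82.7, chaetocin replicate 3 at 32.2 and combination replicate 3 at 28.1, and all other libraries between -34.8 and -3.3.

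**Figure D1:**
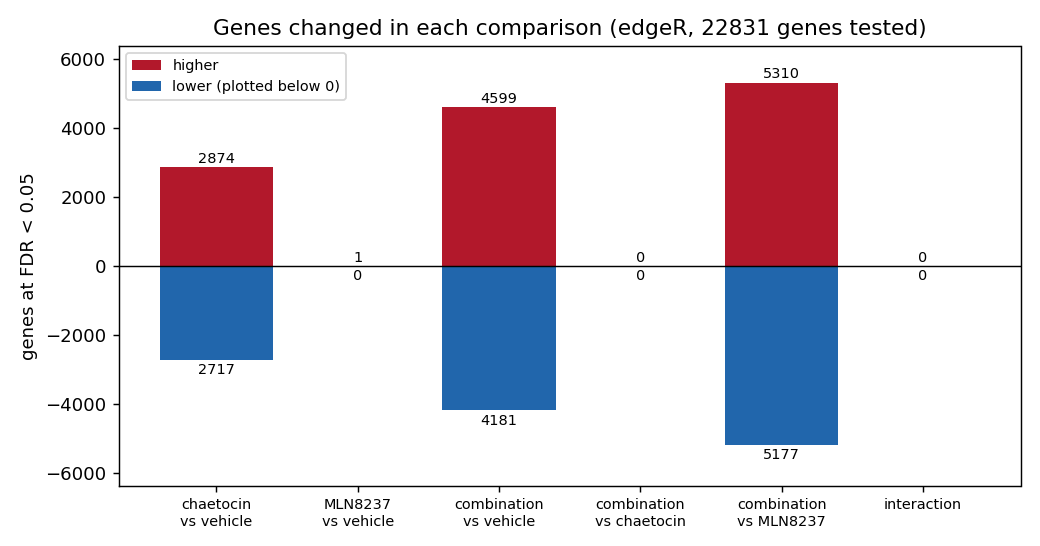
Number of genes at an edgeR adjusted p under 0.05 (y axis) in each comparison (x axis), with higher genes as bars above 0 and lower genes as bars below 0. Bars are long for the comparisons that differ in chaetocin, such as 2874 higher and 2717 lower for chaetocin against vehicle, and at 0 or 1 for the others.

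The comparison of chaetocin with vehicle asked what the compound alone does to transcript levels. Genes of the oxidative stress response carried by the transcription factor NRF2 rose together: 28 of 34 measured members rose and 0 fell, or 29 and 1 adjusted over the list alone, with a median log2 fold change of 1.09 (camera adjusted p = 8.29e-16, and adjusted p = 0.17 with an estimated correlation). HMOX1 (ENSG00000100292, chromosome 22, 35776354 to 35790207), which encodes the haem-degrading enzyme haem oxygenase 1, rose from 95.2 ± 24.4 to 835 ± 188 CPM (n = 3), a log2 fold change of 3.13 ± 0.283 (SE, edgeR adjusted p = 1.14e-05). GCLM (ENSG00000023909, chromosome 1, 94350761 to 94374966) and GCLC, the subunits of the enzyme that starts glutathione synthesis, rose by 1.61 ± 0.0797 and 1.83 ± 0.108 on the log2 scale (edgeR adjusted p = 3.15e-07 and 8.99e-07). OSGIN1 rose by 2.85 ± 0.214 (edgeR adjusted p = 3.06e-06). TXNRD1, which encodes the thioredoxin reductase that chaetocin is known to inhibit, rose by 1.27 ± 0.139 on the log2 scale from 740 ± 42.8 CPM, and SLC7A11, a subunit of the cystine transporter, rose from 40.3 ± 12.4 to 126 ± 4.72 CPM. GCLC, OSGIN1, TXNRD1 and SLC7A11 overlap other genes in the table, so part of their reads could be counted to a neighbour.

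Heat shock and immediate early genes also shifted up with chaetocin. Of 24 heat shock genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 7.7e-05, and adjusted p = 0.205 with an estimated correlation). DNAJB4 rose from 16.9 ± 0.294 to 34 ± 1.02 CPM and HSPH1 from 288 ± 1.8 to 403 ± 18.4 CPM. HSPA1A rose by 0.83 ± 0.15 on the log2 scale, but shares reads with a near-identical copy and overlaps HSPA1L. Of 27 immediate early genes, which respond to growth and stress signals, 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 2.32e-05, and adjusted p = 0.17 with an estimated correlation). EGR1 rose from 2.93 ± 0.899 to 12.7 ± 1.39 CPM, FOSB from 1.12 ± 0.212 to 8.05 ± 1.16 CPM and NR4A1 from 0.931 ± 0.0545 to 6.16 ± 0.997 CPM. The unfolded protein and integrated stress response went both ways: 8 of 40 rose and 9 fell, or 10 and 12 adjusted over the list alone (camera adjusted p = 0.856). ATF3 rose from 5.55 ± 0.131 to 15.8 ± 1.45 CPM and HSPA5, the main chaperone of the endoplasmic reticulum, fell from 638 ± 5.63 to 345 ± 3.34 CPM. DNAJB4, FOSB, NR4A1 and ATF3 overlap other genes.

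The lists of secretory, epithelial and mesenchymal genes shifted down with chaetocin, with members in both directions. With no filter the median was -0.03 for secretory and -0.23 for epithelial genes. PLAU (ENSG00000122861, chromosome 10, 75668935 to 75677255), which encodes the protease urokinase, dropped by 1.68 ± 0.0865 on the log2 scale, from 502 ± 9.74 to 157 ± 2.73 CPM (edgeR adjusted p = 3.15e-07). The chemokine gene CCL2 went from 90 ± 14 to 16.3 ± 2.48 CPM, CX3CL1 from 33.9 ± 4.89 to 7.37 ± 0.823 CPM, and the adhesion gene ICAM1 from 187 ± 4.05 to 58.5 ± 2.57 CPM, while the cytokine gene IL18 rose from 45 ± 0.997 to 140 ± 20.7 CPM. Of 38 NF-kB and secretory genes 6 rose and 16 fell, or 6 and 17 adjusted over the list alone (median log2 fold change -0.34, mean -0.03, camera adjusted p = 0.00908, and adjusted p = 0.17 with an estimated correlation). Of 33 epithelial genes 4 rose and 15 fell, or 5 and 15 adjusted over the list alone (median -0.35, camera adjusted p = 0.0136, and adjusted p = 0.17 with an estimated correlation). The tight junction gene CLDN1 fell from 71.5 ± 3.03 to 21.9 ± 0.526 CPM and the keratin genes KRT8 and KRT18 from 2290 ± 181 to 1220 ± 89.1 CPM and from 1630 ± 127 to 902 ± 13.7 CPM, whereas CLDN4 rose from 49.3 ± 2.58 to 111 ± 12.8 CPM. Of 36 mesenchymal genes 3 rose and 12 fell, or 4 and 13 adjusted over the list alone (median -0.25, camera adjusted p = 0.00289, and adjusted p = 0.17 with an estimated correlation). SPARC (ENSG00000113140, chromosome 5, 151040657 to 151066726), a matrix protein gene, fell from 116 ± 2.06 to 45.3 ± 1.51 CPM, and the hyaluronan receptor gene CD44 from 1690 ± 4.18 to 670 ± 49.6 CPM. PLAU, CCL2, ICAM1, IL18, KRT8, KRT18, SPARC and CD44 overlap other genes, and KRT8 and KRT18 overlap each other.

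Genes of cholesterol and fatty acid synthesis fell: 16 of 32 fell and 1 rose, or 17 and 1 adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 3.07e-05, and adjusted p = 0.273 with an estimated correlation). SREBF1, a regulator of lipid synthesis, fell from 98.5 ± 11.7 to 53 ± 7.82 CPM, TM7SF2 from 10.9 ± 1.02 to 4.35 ± 0.226 CPM and CYP51A1 from 157 ± 5.78 to 104 ± 9.24 CPM, and each overlaps another gene. Mitotic genes rose: 15 of 60 rose and 0 fell, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.000147, and adjusted p = 0.279 with an estimated correlation), among them SKA1, from 37.4 ± 2.05 to 54.7 ± 2.59 CPM, and SPC25 and CDC25C, which overlap other genes, by 0.71 ± 0.0968 and 0.48 ± 0.101 on the log2 scale. Of 56 histone genes 18 rose and 4 fell, or 21 and 4 adjusted over the list alone (median 0.69, camera adjusted p = 7.7e-05, and adjusted p = 0.205 with an estimated correlation). With the stricter filter 23 histone genes were measured and their median was 0.41. HIST1H3B, a replication-dependent histone gene with near-identical copies, rose from 0.32 ± 0.0857 to 1.49 ± 0.26 CPM, while the linker histone genes H1F0 and H1FX fell from 138 ± 0.941 to 78.4 ± 0.385 CPM and from 72.6 ± 4.52 to 46.2 ± 2.13 CPM. H1FX overlaps H1FX-AS1.

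Genes that PANC-1 cells barely expressed in vehicle were detected with chaetocin. MLC1 (ENSG00000100427, chromosome 22, 50497820 to 50524331) went from 0.0383 ± 0.0366 CPM, resting on 6 counts, to 6.85 ± 3.65 CPM, and the mucin gene MUC5AC from 0.203 ± 0.182 to 8.81 ± 4.89 CPM. HKDC1 rose from 0.919 ± 0.414 to 14 ± 2.12 CPM, the non-coding LUCAT1 from 1.08 ± 0.41 to 15.3 ± 2.91 CPM, and PAX5, a B-cell transcription factor gene, from 0.738 ± 0.115 to 8.26 ± 0.49 CPM. HKDC1, LUCAT1 and PAX5 overlap other genes. Of 148 members of the germline list found in the deposited table, 94 had a count in some library and 24 passed the expression filter, and of these 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (median log2 fold change 0.70, also with the 4 members at 0 counts in vehicle set to their bound, camera adjusted p = 7.7e-05, and adjusted p = 0.17 with an estimated correlation). SSX1 had 0 counts in vehicle and was at least 69.2-fold higher, and PIWIL2, a germline gene of the piRNA pathway, rose from 0.824 ± 0.298 to 2.56 ± 0.408 CPM. Members near 0 in vehicle entered the test through other libraries and had no room to fall, so these counts do not give the list a direction. The germline call was lost with the stricter filter (adjusted p = 0.129, range over camera settings 2.14e-07 to 0.17), where 3 of 12 rose and the median was 0.24. Of 18 members with a vehicle mean of at least 0.178 CPM, a level read from 1 of the groups compared, 6 rose and 0 fell (median 0.35). With no filter 16 of 94 rose and 0 fell (median 0.65). The median lay at percentile 99.7 of 10000 random lists matched on mean expression, and of 6476 tested genes under 1 CPM 969 rose and 178 fell. The germline median was 1.18 without vehicle replicate 1, 1.22 without vehicle replicate 2, 1.35 without chaetocin replicate 1 and 1.12 without chaetocin replicate 2, where 28 to 30 members were measured. TEX10, also matched by its symbol, is expressed outside the germline and rose from 38 ± 3.02 to 60.6 ± 3.96 CPM. Of 12 endothelial markers 6 passed the filter, and of these 3 rose and 0 fell, also when adjusted over the list alone (median 2.34, also with VWF at its bound, camera adjusted p = 0.00689, and adjusted p = 0.172 with an estimated correlation), among them VWF, at least 74.2-fold higher, and ERG, from 1.02 ± 0.231 to 5.87 ± 0.487 CPM, both overlapping other genes. Only 2 endothelial markers had a vehicle mean of at least 0.178 CPM, of which 1 rose, and 3 passed the stricter filter, too few to test. The median of the 6 lay at percentile 99.4 of random lists matched in the same way, with the same limit. In the same libraries the mean RPKM, computed from the counts, over genes silent in vehicle (at most 3 counts over the group) was 0.0108 with chaetocin and 0.00384 with MLN8237.

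SUV39H1, SUV39H2, EHMT2 and AURKA did not pass the test with chaetocin. SUV39H1 stood at 46.9 ± 0.529 CPM in vehicle and 39.1 ± 0.467 with chaetocin (edgeR adjusted p = 0.0792), SUV39H2 at 33.3 ± 1.92 and 37.6 ± 2.2 (adjusted p = 0.136), EHMT2 at 59 ± 1.81 and 50.8 ± 2.96 (adjusted p = 0.138), and AURKA at 206 ± 6.08 and 205 ± 10.1 (adjusted p = 0.94). Fitting only the groups compared gave SUV39H1 an adjusted p = 0.00989 (range over alternatives 0.00989 to 0.199) and EHMT2 0.0417 (0.0417 to 0.331). SUV39H1 also passed with length-trend offsets (0.0481), an alternative chosen after seeing the data. Without the 3 treated libraries numbered 3, likewise chosen after, SUV39H2 had 0.0461 (range 0.0461 to 0.404). Other methyltransferase genes of the H3K9 list passed. SETDB2 fell from 8.85 ± 0.419 to 6.25 ± 0.294 CPM and SUV420H1, of histone H4, from 61.4 ± 1.77 to 50.1 ± 1.74 CPM, while SETDB1 rose from 38.6 ± 2.64 to 48.5 ± 1.4 CPM (edgeR adjusted p = 0.0068, 0.0135 and 0.0194). SETDB1 missed the threshold without vehicle replicate 1 (0.0949) or 3 (0.0603) or chaetocin replicate 1 (0.063) or 2 (0.0721), over a range of 0.00273 to 0.0949. SUV420H1 missed it with no filter (0.105) and without vehicle replicate 3 (0.0527) or chaetocin replicate 2 (0.0659), over a range of 0.000545 to 0.105. SUV39H1, SUV39H2, EHMT2, SETDB1 and SETDB2 overlap other genes.

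The following lists did not pass the camera test with chaetocin. Of 21 genes of H3K9 methylation and heterochromatin 4 rose and 2 fell (adjusted p = 0.856), and of 17 Aurora kinase genes 2 rose (adjusted p = 0.577), with the same counts adjusted over the list alone. Of 49 genes of G1/S and DNA replication 5 rose (adjusted p = 0.331), and of 33 DNA repair genes 5 rose (adjusted p = 0.259), with the same counts adjusted over the list alone. Both lists passed upward without the treated libraries numbered 3 (0.0269 and 0.0201, ranges over camera settings 0.0269 to 0.958 and 0.0201 to 0.872). Among 28 p53 targets 5 rose and 5 fell (adjusted p = 0.897), with PERP down from 1110 ± 49.7 to 432 ± 21.4 CPM and MDM2, which overlaps other genes, up from 99.4 ± 4.9 to 139 ± 3.07 CPM. Metallothioneins, which share near-identical sequences, gave 2 higher and 4 lower of 9 (adjusted p = 0.331), hypoxia genes 7 and 6 of 32 (adjusted p = 0.856), apoptosis regulators 11 and 6 of 37 (adjusted p = 0.404), and Polycomb and DNA methylation enzymes 5 and 3 of 26 (adjusted p = 0.856), with the same counts adjusted over the list alone. Interferon-stimulated genes gave 11 higher and 13 lower of 49, or 13 and 14 adjusted over the list alone (adjusted p = 0.897), ZNF genes 84 and 29 of 493, or 81 and 28 (adjusted p = 0.138), and autophagy and lysosome 10 and 9 of 39, or 11 and 10 (adjusted p = 0.897). Of 148 ribosomal protein genes 4 rose, or 1 adjusted over the list alone (adjusted p = 0.856), and of 37 mitochondria-encoded genes 2 rose, or 0 adjusted over the list alone (adjusted p = 0.569). Immune markers gave 2 higher of 13 (adjusted p = 0.138, 0.0423 without vehicle replicate 3 and 0.0454 without chaetocin replicate 1, range over camera settings 0.0423 to 0.741). Endocrine markers gave 2 higher and 5 lower of 12 (adjusted p = 0.193), both lists with the same counts adjusted over the list alone, and ductal markers 3 and 5 of 14, or 4 and 7 (adjusted p = 0.499). Only 3 acinar markers were measured, of which 1 rose, and they were not tested as a list. The median, mean and camera direction differed in sign for the lists of heterochromatin, p53, unfolded protein, hypoxia, interferon, Polycomb, autophagy, ribosomal and ductal genes.

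In all, 5591 of 22831 genes changed with chaetocin, 2874 higher and 2717 lower, and 1463 and 526 of them by more than 2-fold. With vehicle replicate 2 left out the count was 3704. No list passed with an estimated correlation.

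**Figure D2:**
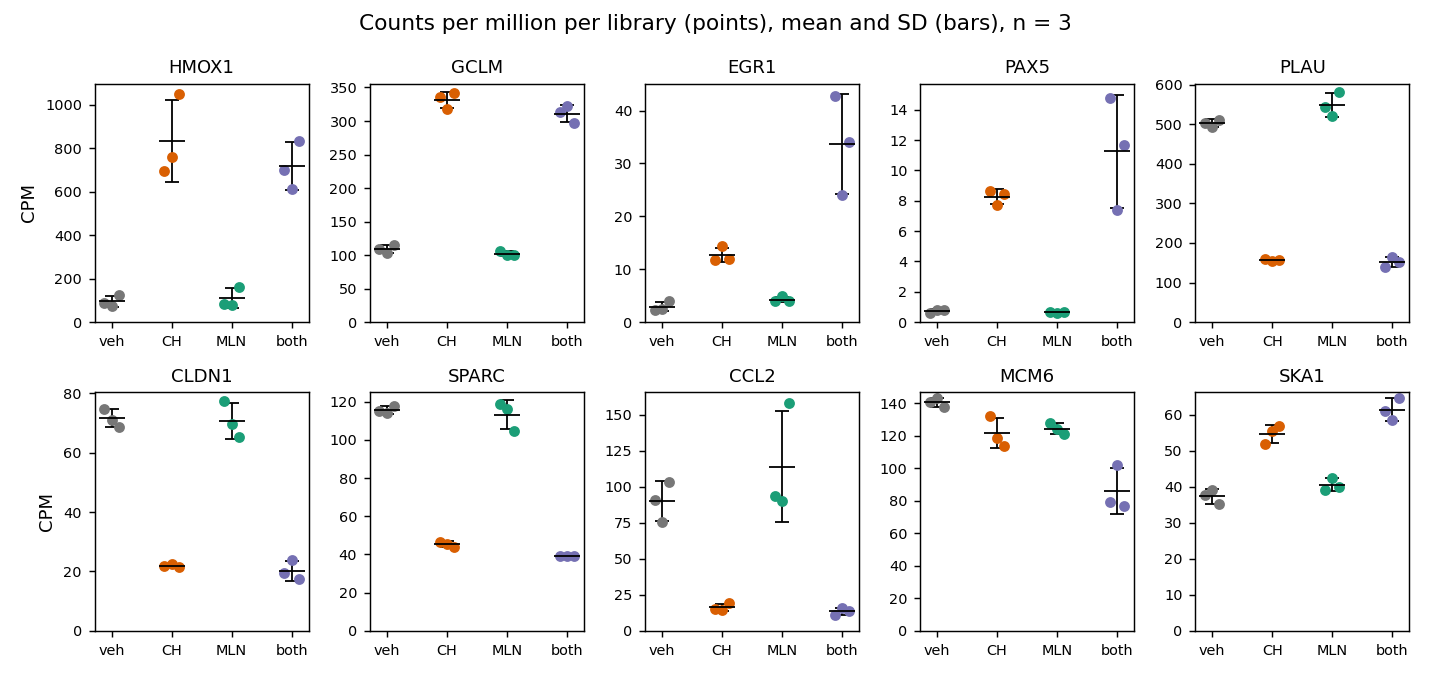
CPM of 10 genes (y axes, linear) in vehicle (veh), chaetocin (CH), MLN8237 (MLN) and combination (both) libraries, with a point per library and bars for the mean and SD (n = 3). Means of HMOX1 were 95.2 and 110 CPM in vehicle and MLN8237 and 835 and 717 CPM with chaetocin and both.

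The comparison of MLN8237 with vehicle asked what the Aurora A inhibitor does alone. Of 22831 genes 1 passed, so values of the others are given without a call. AURKA, which encodes Aurora A, stood at 206 ± 6.08 CPM in vehicle and 245 ± 9.13 with MLN8237 (log2 fold change 0.25 ± 0.0858, edgeR adjusted p = 0.516). Mitotic genes had a median log2 fold change of 0.10 over 60 members, with NDC80, a kinetochore gene, at 71.7 ± 0.694 and 92.1 ± 13.5 CPM, and FAM64A at 68.3 ± 4.54 and 91.2 ± 8.72 CPM (camera adjusted p = 0.000544, and adjusted p = 0.633 with an estimated correlation). Ribosomal protein genes had a median of 0.35 over 148 members (camera adjusted p = 1.74e-13, and adjusted p = 0.633 with an estimated correlation), and of 0.10 without MLN8237 replicate 3. RPS29 stood at 221 ± 33.6 and 326 ± 117 CPM, and at 461 CPM in MLN8237 replicate 3, the library that stood apart on the component above and in which ribosomal protein genes held 6.24% of counts against 4.07% and 4.29% in its group mates.

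Metallothioneins (9 genes, median log2 change 0.49) and interferon-stimulated genes (49 genes, median 0.13) were higher relative to other genes with MLN8237, and ZNF genes (493 genes, median -0.08) lower, with camera adjusted p = 0.0255, 0.0255 and 0.0216 (each adjusted p = 0.633 with an estimated correlation). MT2A stood at 647 ± 65.6 and 916 ± 379 CPM, PSMB8 at 31 ± 2.62 and 41.9 ± 9.34 CPM and ZNF91 at 11.6 ± 0.292 and 9.17 ± 1.01 CPM. No member of these 5 lists passed, over all genes or adjusted over the list alone. Without MLN8237 replicate 3 the adjusted p was 0.326 for metallothioneins and 0.119 for ZNF genes. Without vehicle replicate 3 it was 0.0514 for mitotic genes, metallothioneins and ZNF genes and 0.215 for interferon-stimulated genes. Mitotic genes also missed the threshold without MLN8237 replicate 2 (0.0866), metallothioneins without vehicle replicate 2 (0.118), and interferon-stimulated genes without MLN8237 replicate 1 (0.13) or 2 (0.271). The slope of log2 CPM on log2 gene length was -0.187 in MLN8237 replicate 3 and -0.074 to 0.070 in the other 11 libraries. With each library's length trend removed the adjusted p was 0.049 for metallothioneins and interferon-stimulated genes and 0.0573 for ZNF genes. Without the treated libraries numbered 3 it was 0.209 for metallothioneins and 0.122 for ZNF genes, and with the stricter filter 0.0802 for interferon-stimulated genes. Over camera settings the lowest values were 7.19e-12 for mitotic genes, 0.00736 for metallothioneins and ZNF genes and 1.05e-05 for interferon-stimulated genes, and the highest was 0.633 for each. Medians without MLN8237 replicate 3 were 0.11 for metallothioneins and -0.03 for ZNF genes, and without vehicle replicate 3 they were 0.06 for mitotic and for interferon-stimulated genes. The ribosomal protein list passed with each library left out in turn. Endothelial and ductal markers passed only without MLN8237 replicate 3 among those fits (0.0291 each, against 0.112 and 0.092 with it, ranges 0.00729 to 0.633 and 0.0177 to 0.633). PSMB8, ZNF91, NDC80, FAM64A and RPS29 overlap other genes, and RPS29 and MT2A have near-identical copies.

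A count of 1 gene passed with MLN8237, against 1938 at an unadjusted p under 0.05 by edgeR, and DESeq2 and limma-voom also called 1. The 1938 became 619 without MLN8237 replicate 3, 749 without vehicle replicate 3, 797 without vehicle replicate 2 and 4667 without MLN8237 replicate 1. It was the processed pseudogene RP3-375P9.2 (ENSG00000217130, chromosome 6, 34711953 to 34712450), which fell outside the rule for named genes and was chosen after its values were seen. RP3-375P9.2 rose from 0.121 ± 0.0222 to 1.44 ± 0.332 CPM (log2 fold change 3.55 ± 0.36, edgeR adjusted p = 0.00431), and stood at 0.131 ± 0.0514 CPM with both compounds. As a pseudogene it can take reads from its parent gene. The call was lost in a fit of only the groups compared (adjusted p = 0.105) and without vehicle replicate 2 (0.0799) or vehicle replicate 3 (0.0816), over a range of alternatives from 2.18e-10 to 0.105. The genes with the smallest p under the rule, TNFAIP8L1 (log2 fold change 0.50 ± 0.112), CDKN3 (0.33 ± 0.0846), ATP2B4 (-0.38 ± 0.103), DMTF1 (-0.34 ± 0.0982) and PCNT (-0.36 ± 0.106), each had an edgeR adjusted p = 0.516, as did TXNRD1 (-0.31 ± 0.137) and EHMT2 (-0.16 ± 0.0992). Of these only CDKN3 overlaps no other gene. SUV39H1 (0.11 ± 0.101) and SUV39H2 (-0.03 ± 0.0808) had adjusted p = 0.604 and 0.878.

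The combination was compared with vehicle to ask what both compounds do together. The NRF2 and heat shock genes rose, as did mitotic, histone and immediate early genes. Of 34 NRF2 targets 26 rose and 0 fell, or 27 and 1 adjusted over the list alone (median log2 fold change 1.08, camera adjusted p = 9.01e-11, and adjusted p = 0.175 with an estimated correlation), with GCLM at 311 ± 12.7 CPM against 109 ± 5.85 in vehicle and the drug exporter gene ABCC2, which overlaps another gene, at 23.2 ± 5.89 against 2.32 ± 0.651. Of 60 mitotic genes 38 rose and 0 fell, or 42 and 0 adjusted over the list alone (median 0.34, camera adjusted p = 5.66e-08, and adjusted p = 0.175 with an estimated correlation), with CDCA2 from 25 ± 1.57 to 42.4 ± 4.05 CPM and SKA1 from 37.4 ± 2.05 to 61.5 ± 3.07 CPM. Of 56 histone genes 34 rose and 4 fell, or 37 and 4 adjusted over the list alone (median 1.14, camera adjusted p = 1.01e-06, and adjusted p = 0.175 with an estimated correlation), HIST1H3B reaching 3.48 ± 1.27 CPM, and a median of 0.75 over 23 with the stricter filter. Of 27 immediate early genes 16 rose and 3 fell, or 17 and 3 adjusted over the list alone (median 0.60, camera adjusted p = 8.94e-05, and adjusted p = 0.196 with an estimated correlation), with EGR1 at 33.7 ± 9.39 CPM (log2 fold change 3.52 ± 0.238, edgeR adjusted p = 1.41e-06) and FOSB, which overlaps ERCC1, at 17.1 ± 4.81 CPM.

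Genes of DNA replication fell with the combination: 19 of 49 fell and 2 rose, also when adjusted over the list alone (median log2 fold change -0.16, camera adjusted p = 0.00204, and adjusted p = 0.595 with an estimated correlation), a call lost with the stricter filter (0.0502, median -0.09, range 1.24e-05 to 0.595). The helicase subunit genes MCM6 and MCM5 fell from 140 ± 2.64 to 86 ± 14 CPM and from 134 ± 2.06 to 88.2 ± 12.5 CPM, while CCNE1, the gene of cyclin E1, rose from 29.8 ± 0.805 to 42.5 ± 3.69 CPM. Of 32 cholesterol and fatty acid genes 18 fell and 1 rose, also when adjusted over the list alone (median -0.57, camera adjusted p = 5.91e-05, and adjusted p = 0.309 with an estimated correlation), with CYP51A1 at 84.7 ± 12.2 CPM. Of 33 epithelial genes 16 fell and 4 rose, also when adjusted over the list alone (median -0.46, camera adjusted p = 0.00407, and adjusted p = 0.175 with an estimated correlation), with CLDN1 at 20.2 ± 3.31 CPM. Of 36 mesenchymal genes 14 fell and 4 rose, or 17 and 4 adjusted over the list alone (median -0.35, camera adjusted p = 0.00668, and adjusted p = 0.175 with an estimated correlation), with SPARC at 39.2 ± 0.137 CPM. Heat shock genes gave 13 higher and 1 lower of 24, or 14 and 1 adjusted over the list alone (median 0.34, camera adjusted p = 0.000703, and adjusted p = 0.304 with an estimated correlation), with DNAJB4 at 45.5 ± 5.37 CPM. CYP51A1, SPARC and DNAJB4 overlap other genes.

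Of the 148 germline genes the 24 that passed the filter gave 13 higher and 0 lower with the combination, or 14 and 0 adjusted over the list alone (median log2 fold change 0.94, also with members at 0 in vehicle at their bound, camera adjusted p = 8.94e-05, and adjusted p = 0.175 with an estimated correlation), with SSX1 at least 126-fold higher and TEX19 up from 0.23 ± 0.0759 to 1.5 ± 0.292 CPM. As with chaetocin, members near 0 in vehicle had no room to fall. The germline call was lost with the stricter filter (0.0823, range 3.52e-06 to 0.175), where 5 of 12 rose and the median was 0.15. Of the 18 members with a vehicle mean of at least 0.178 CPM 7 rose (median 0.41), and with no filter 20 of 94 rose and 1 fell (median 1.81). The median lay at percentile 99.6 of matched random lists, and of 6476 tested genes under 1 CPM 1770 rose and 266 fell. Of 12 endothelial markers 6 passed the filter and 4 of these rose, also when adjusted over the list alone (median 2.61, also with VWF at its bound, camera adjusted p = 0.00661, and adjusted p = 0.176 with an estimated correlation), VWF being at least 160-fold higher, with 1 of the 2 at or above 0.178 CPM in vehicle among them and the median at percentile 98.9 of matched random lists. MLC1 reached 17.8 ± 10.2 CPM, MUC5AC 27.5 ± 17.3 and GREB1 13.4 ± 5.26, against 0.0383, 0.203 and 0.834 CPM in vehicle. The mean RPKM, computed from the counts, over genes silent in vehicle was 0.0194 in these libraries. Of 493 ZNF genes 148 rose and 53 fell, or 151 and 55 adjusted over the list alone (median 0.14, camera adjusted p = 0.0248, and adjusted p = 0.614 with an estimated correlation), a call lost without vehicle replicate 1 (0.111) or combination replicate 1 (0.0878) or with no filter (0.244), over a range of 0.000458 to 0.614. Ribosomal protein genes gave 9 each way of 148, or 8 higher and 3 lower adjusted over the list alone (median -0.22, mean -0.03, camera adjusted p = 0.0287, and adjusted p = 0.835 with an estimated correlation), a call also lost without vehicle replicate 1 (0.247) or combination replicate 1 (0.437, median -0.12) or with no filter (0.178, median -0.03), over a range of 0.000373 to 0.835. Of 13 immune markers 4 rose, or 2 adjusted over the list alone (camera adjusted p = 0.064, range 0.00813 to 0.614), and the list passed without vehicle replicate 3 (0.0258) or combination replicate 2 (0.00813). VWF and GREB1 overlap other genes.

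Among the secreted genes CX3CL1 fell to 5.09 ± 1.84 CPM, CCL2 to 13.5 ± 2.3 and PLAU to 152 ± 13 with the combination, but the list of 38 did not pass (12 higher and 17 lower, also when adjusted over the list alone, median -0.34, mean 0.22, camera adjusted p = 0.139). PLCH2, B3GNT7 and CXXC5 were among the largest decreases, at 30.3 ± 12.3, 11 ± 4.41 and 13.6 ± 6.85 CPM against 160 ± 24.1, 63.8 ± 5.36 and 65 ± 1.95 in vehicle. EHMT2 fell from 59 ± 1.81 to 42 ± 2.87 CPM (edgeR adjusted p = 0.00183), and TXNRD1 rose to 1620 ± 173 CPM (edgeR adjusted p = 6.11e-05). AURKA (log2 fold change 0.26 ± 0.0858, edgeR adjusted p = 0.0298), SUV39H1 (-0.33 ± 0.101, adjusted p = 0.0206) and SUV39H2 (0.24 ± 0.0806, adjusted p = 0.0315) passed. Their ranges over alternatives were 0.00535 to 0.157, 0.00225 to 0.114 and 0.00432 to 0.206. AURKA missed the threshold with no filter (0.157) and without vehicle replicate 1 (0.0735), 2 (0.0799) or 3 (0.117) or combination replicate 2 (0.123) or 3 (0.0537). SUV39H1 missed it without combination replicate 1 (0.114) or 3 (0.0612). SUV39H2 missed it with no filter (0.206) and without vehicle replicate 2 (0.115) or 3 (0.143) or combination replicate 1 (0.0546), 2 (0.0764) or 3 (0.0695). CCL2, PLAU, PLCH2, CXXC5, EHMT2, TXNRD1, SUV39H1 and SUV39H2 overlap other genes. In all, 8780 genes changed, 4599 higher and 4181 lower, and 2523 and 883 of them by more than 2-fold.

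**Figure D3:**
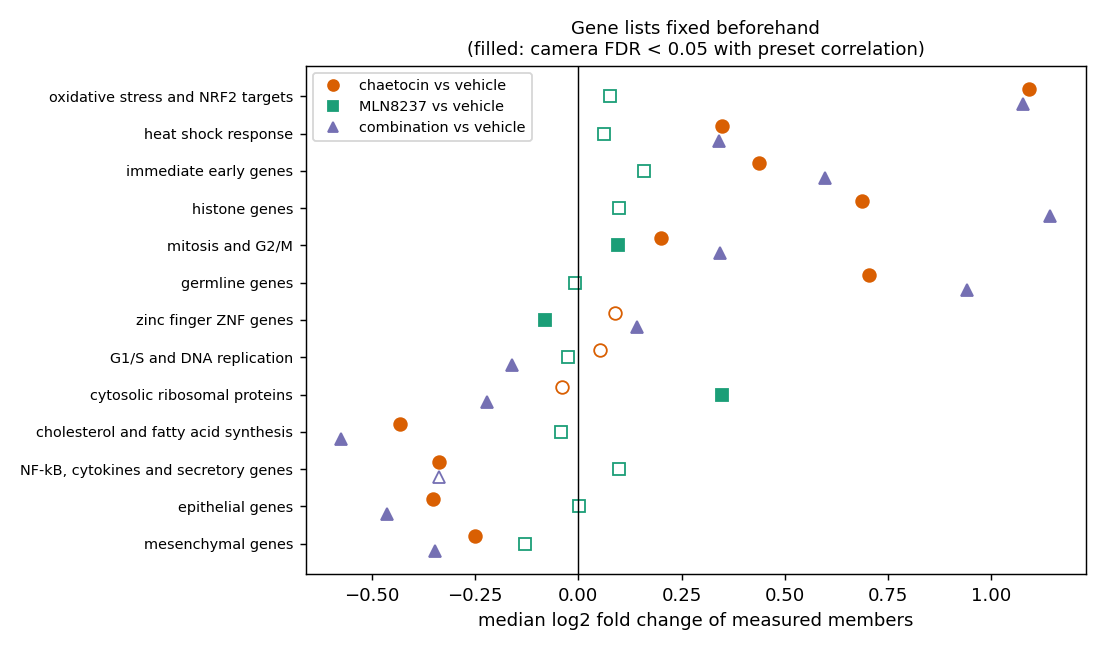
Median log2 fold change over measured members (x axis) of 13 gene lists (y axis) for each treatment against vehicle, filled where camera with the preset correlation gave an adjusted p under 0.05. NRF2 targets lie at 1.09 with chaetocin and 1.08 with the combination, and G1/S genes at 0.05 and -0.16.

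Chaetocin and the combination shared 2664 genes higher and 2475 lower against vehicle and 0 in opposite directions. Independent lists of those sizes would share 579 and 498. The 0 shared in 20 simulations of unchanged groups sharing vehicle was built in. The log2 fold changes had a covariance across genes of 1.0089 against 0.0728 simulated, a difference of 0.9360, and a correlation of 0.948 against 0.523. Genes are not independent replicates, the 3 vehicle libraries are shared and cannot be split, and part of the excess may come from them. Chaetocin and MLN8237 shared 0 genes, against 0.126 higher and 0 lower for independent lists (covariance 0.1122 against 0.0715 simulated, correlation 0.242 against 0.503), with 5591 and 1 genes called by edgeR, and 0 also by DESeq2 and limma-voom. MLN8237 and the combination shared 0 genes, against 0.201 higher and 0 lower for independent lists, with a covariance of 0.1002 against 0.0718 and a correlation of 0.176 against 0.505.

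The combination was compared with chaetocin to ask what MLN8237 adds. The replication genes lay lower with the combination, with a median log2 difference of -0.27 over 49 members (camera adjusted p = 1.13e-18, and adjusted p = 0.312 with an estimated correlation). By edgeR 0 members passed over all genes and 23 were lower adjusted over the list alone. MCM6 stood at 122 ± 9.47 CPM with chaetocin and 86 ± 14 with both, MCM5 at 124 ± 0.651 and 88.2 ± 12.5, and MCM3 at 269 ± 6.81 and 207 ± 17.8 (edgeR adjusted p = 0.203 each). Mitotic genes lay higher (median 0.16 over 60, camera adjusted p = 2.76e-08, and adjusted p = 0.312 with an estimated correlation), with 3 higher adjusted over the list alone, and CDCA2 at 32.2 ± 1.69 and 42.4 ± 4.05 CPM. Histone genes lay higher (median 0.50 over 56, camera adjusted p = 1.36e-05, and adjusted p = 0.312 with an estimated correlation), with 5 higher and 2 lower adjusted over the list alone. The histone median was 0.29 without combination replicate 1 and 0.31 without combination replicate 3, and 0.32 with the stricter filter.

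Immediate early genes had a median of 0.20 against chaetocin alone (27 genes, camera adjusted p = 0.0272, and adjusted p = 0.53 with an estimated correlation), with 11 higher and 3 lower adjusted over the list alone. EGR1 stood at 12.7 ± 1.39 and 33.7 ± 9.39 CPM (edgeR adjusted p = 0.165), FOS at 2.07 ± 0.667 and 5.61 ± 1.21 CPM, and LPAR6, a lysophosphatidic acid receptor gene inside RB1, at 6.88 ± 1.54 and 23.3 ± 8.36 CPM (edgeR adjusted p = 0.129). TNFRSF10D, a decoy receptor gene for the death ligand TRAIL, stood at 21.4 ± 3.22 and 46.2 ± 12.2 CPM, and EDN1, the endothelin 1 gene, at 23.3 ± 0.85 and 16 ± 1.3 CPM. TNFRSF10D, FOS, C6orf132 (-0.64 ± 0.11) and LPCAT4 (-0.46 ± 0.0843) had edgeR adjusted p = 0.182, and EDN1 0.165. Ribosomal protein genes had a median of -0.18 over 148 (camera adjusted p = 5.14e-05, and adjusted p = 0.675 with an estimated correlation). They lost their call with no filter (0.102) and without combination replicate 1 (0.146, median -0.09, lowest over camera settings 2.07e-07). The immediate early genes lost theirs without chaetocin replicate 1 (0.12) or combination replicate 3 (0.131, lowest 0.00385) or the treated libraries numbered 3 (0.0665). Their median was 0.31 without chaetocin replicate 3, 0.35 without combination replicate 2 and 0.12 without combination replicate 3.

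Smaller shifts passed against chaetocin for germline (median 0.20), autophagy (0.07), epithelial (-0.12), Polycomb (-0.10), ZNF (0.06) and NF-kB and secretory genes (0.12). Their camera adjusted p were 0.0272, 0.0272, 0.0272, 0.04, 0.04 and 0.0466, and adjusted p = 0.427, 0.53, 0.312, 0.53, 0.66 and 0.427 with an estimated correlation. By edgeR 0 members passed over all genes. Adjusted over the list alone, 1 germline gene was higher, 1 Polycomb gene higher and 1 lower, and 0 in the other lists. Each of these calls was lost when some library was left out. Germline genes lost it without chaetocin replicate 2 (0.0725) or combination replicate 3 (0.172). Autophagy genes lost it without chaetocin replicate 1 (0.173) or 2 (0.134) or combination replicate 3 (0.339), and epithelial genes without chaetocin replicate 1 (0.0507) or 2 (0.089) or combination replicate 1 (0.0582) or 3 (0.0826). Polycomb genes lost it without chaetocin replicate 1 (0.154) or 2 (0.0874) or combination replicate 3 (0.49), and ZNF genes without chaetocin replicate 2 (0.1) or 3 (0.344) or combination replicate 1 (0.518) or 2 (0.0549). NF-kB genes lost it without chaetocin replicate 1 (0.155) or 2 (0.1) or combination replicate 2 (0.15) or 3 (0.172). The stricter filter also ended the calls of germline (0.238), epithelial (0.0964), Polycomb (0.0964) and NF-kB genes (0.256), and no filter those of autophagy (0.285, median 0.04), ZNF (0.523, median 0.03) and NF-kB genes (0.393, median 0.08). Length-trend offsets ended those of autophagy (0.0503), ZNF (0.0629) and NF-kB genes (0.054), and leaving out the treated libraries numbered 3 those of germline (0.0977) and Polycomb genes (0.0857). The lowest values over camera settings were, in the order named first, 0.00172, 0.00109, 0.00385, 0.0063, 0.00122 and 0.0107. Some medians moved by over 1.5 times. That of NF-kB genes was 0.04, 0.06 and 0.05 without chaetocin replicate 1, chaetocin replicate 2 and combination replicate 3. That of ZNF genes was 0.02 without combination replicate 1. Without chaetocin replicate 1, combination replicate 2 and combination replicate 3 the Polycomb median was -0.05, -0.20 and 0.00 and the autophagy median 0.02, 0.12 and 0.02, the latter also 0.05 without chaetocin replicate 2.

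Some lists that did not pass against chaetocin did so when a library was left out. Mitochondria-encoded genes did so without chaetocin replicate 1 (0.00374, range over camera settings 0.00374 to 0.781), and DNA repair genes without chaetocin replicate 3 (0.014, range 0.014 to 0.995). Cholesterol and fatty acid genes passed without chaetocin replicate 3 (0.0129) or combination replicate 2 (0.0139), over a range of 0.0129 to 0.675. Immune and endothelial markers passed without combination replicate 2 (0.0139 and 0.0172, ranges 0.0139 to 0.997 and 0.0172 to 0.53).

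By edgeR 0 genes passed between the combination and chaetocin, with 2677 at an unadjusted p under 0.05, 296 called by DESeq2 and 1 by limma-voom. The 2677 became 1246 without combination replicate 1, 4338 without combination replicate 2 and 4267 without MLN8237 replicate 3. Without combination replicate 2, 573 passed (281 higher, 292 lower), though removing the combination library nearest chaetocin favours such calls. Among the 573 were LPAR6 (edgeR adjusted p = 0.00316, range over alternatives 3.88e-08 to 0.797) and MCM6 (0.0104, range 0.00701 to 0.876). EGR1 and EDN1 (0.0104, range 2.28e-06 to 0.876), TNFRSF10D (0.0084, range 4.09e-05 to 0.876) and FOS (0.0191, range 0.000409 to 0.876) also passed there. So did C6orf132 (0.0106) and LPCAT4 (0.0133), with ranges of 0.000113 to 0.876, MCM5 (0.0133, range 0.00544 to 0.876) and MCM3 (0.0215, range 0.00595 to 0.876). DESeq2 called each of these 10 as well, and no filter called LPAR6, EGR1, TNFRSF10D, EDN1, FOS and C6orf132. Of 49 replication genes 15 were lower without that library. CDCA2 passed only by DESeq2 (0.0129, range 0.0129 to 0.876). Without MLN8237 replicate 3, an omission chosen after seeing the data, 7 genes passed. AURKA (0.27 ± 0.0858), SUV39H1 (-0.07 ± 0.101), SUV39H2 (0.06 ± 0.0804), EHMT2 (-0.28 ± 0.0993) and TXNRD1 (-0.14 ± 0.137) had edgeR adjusted p = 0.264, 0.823, 0.79, 0.31 and 0.725.

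**Figure D4:**
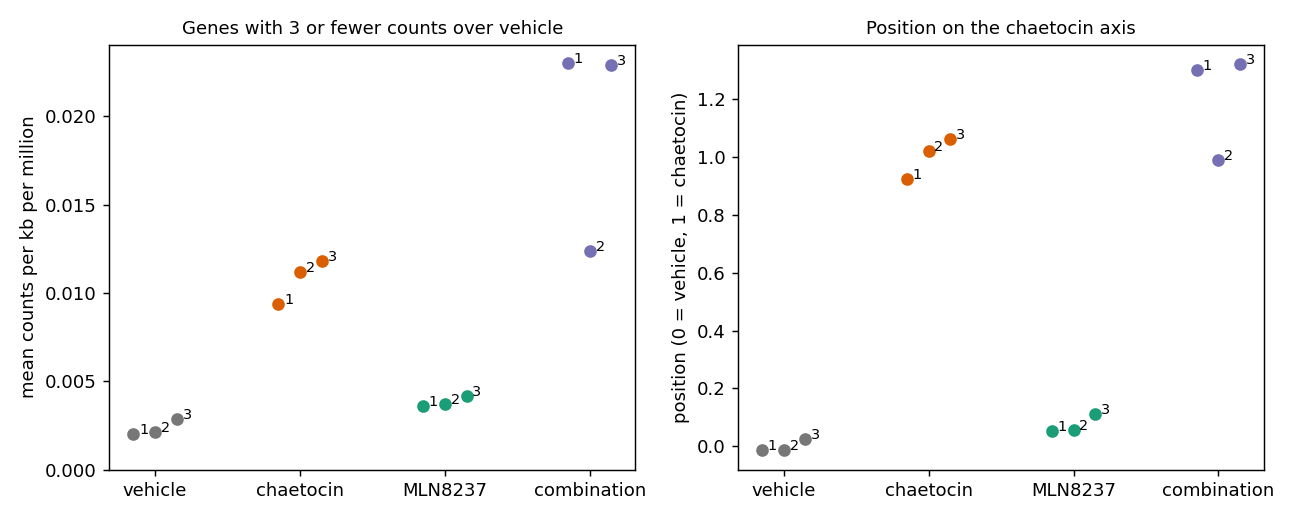
Mean RPKM, computed from the counts, over genes with at most 3 counts over the vehicle group (left, y axis) and position on the axis from vehicle to chaetocin (right, y axis) in each of the 12 libraries, numbered by replicate within their group (x axis). Combination replicate 2 lies at 0.987 on the axis from vehicle (0) to chaetocin (1), against 1.3 and 1.32 for its group mates.

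The combination was compared with MLN8237 to ask what chaetocin adds. Of 34 NRF2 targets 25 rose, also when adjusted over the list alone (median log2 fold change 0.86, camera adjusted p = 1.6e-08, and adjusted p = 0.378 with an estimated correlation), TXNRD1 by 1.44 ± 0.14 on the log2 scale (edgeR adjusted p = 1.19e-05). Of 56 histone genes 36 rose and 4 fell, or 36 and 5 adjusted over the list alone (median 1.26, camera adjusted p = 0.000204, and adjusted p = 0.378 with an estimated correlation), a call lost with the stricter filter (0.29, median 0.30 over 23, range 6.11e-05 to 0.378). Of 60 mitotic genes 29 rose and 0 fell, or 31 and 0 (median 0.24, camera adjusted p = 0.000346, and adjusted p = 0.378 with an estimated correlation). Of 148 ribosomal protein genes 93 fell and 8 rose, or 99 and 10 adjusted over the list alone (median -0.57, camera adjusted p = 7.66e-07, and adjusted p = 0.601 with an estimated correlation). In MLN8237 replicate 3 ribosomal protein genes held 6.24% of counts, against 4.07% and 4.29% in its group mates. Without it 75 of 154 fell and 13 rose, or 79 and 13 adjusted over the list alone (median -0.33), and with no filter the median was -0.29. Of 32 cholesterol and fatty acid genes 19 fell and 2 rose, or 20 and 2 (median -0.52, camera adjusted p = 0.000338, and adjusted p = 0.378 with an estimated correlation). CCL2 fell from 114 ± 38.4 to 13.5 ± 2.3 CPM, CX3CL1 from 37.5 ± 3.63 to 5.09 ± 1.84 and ANO9 from 30.4 ± 2.45 to 4.86 ± 0.353. MLC1, MUC5AC, GREB1, HKDC1 and LUCAT1 rose by 7.52, 6.28, 4.29, 4.23 and 4.19 on the log2 scale. CCL2, ANO9, TXNRD1, GREB1, HKDC1 and LUCAT1 overlap other genes. The mean RPKM over genes silent in vehicle was 0.0194 with both and 0.00384 with MLN8237.

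ZNF genes (198 higher and 56 lower of 493), immediate early genes (14 and 2 of 27) and heat shock genes (12 and 1 of 24) also rose against MLN8237, and germline genes (13 and 1 of 24) and endothelial markers (3 and 0 of 6) passed, with camera adjusted p = 0.00183, 0.00313, 0.01, 0.000327 and 0.0359, and adjusted p = 0.42, 0.378, 0.42, 0.335 and 0.378 with an estimated correlation. Epithelial genes (4 higher, 15 lower of 33), replication genes (3 and 19 of 49), metallothioneins (1 and 5 of 9) and mesenchymal genes (5 and 17 of 36) fell, with camera adjusted p = 0.00481, 0.00715, 0.0359 and 0.0398, and adjusted p = 0.335, 0.557, 0.557 and 0.378 with an estimated correlation. Adjusted over the list alone, ZNF genes gave 201 and 56, epithelial genes 5 and 15, and the others the same counts. The heat shock and mesenchymal calls were lost without MLN8237 replicate 1 (0.0627 and 0.0835), metallothioneins without MLN8237 replicate 3 (0.0789, median -0.59 against -1.10 with it) and endothelial markers without combination replicate 3 (0.0523). The stricter filter ended the calls of replication genes (0.129, median -0.11, range 0.000122 to 0.557), mesenchymal genes (0.129), metallothioneins (0.0748) and germline genes (0.0748, median 0.24, range 1.27e-05 to 0.335). Without the treated libraries numbered 3 replication genes (0.055) and endothelial markers (0.103) lost theirs, and metallothioneins did so with length-trend offsets (0.0624). With no filter the germline median was 1.80 and the epithelial median -0.34, against -0.55. Among matched random lists the germline and endothelial medians lay at percentiles 94.6 and 93.1. The lowest values of the heat shock, mesenchymal, metallothionein and endothelial lists over camera settings were 0.000992, 0.00361, 0.00402 and 0.0124, and the highest were those with an estimated correlation. The germline median of 0.73 was 1.43, 1.22 and 1.74 without MLN8237 replicates 1, 2 and 3 and 1.43 without combination replicate 2, where 29 to 30 members were measured. Immune markers (4 higher, 0 lower of 13, also when adjusted over the list alone, camera adjusted p = 0.146, range 0.0252 to 0.621) passed without MLN8237 replicate 3 (0.0482) or combination replicate 2 (0.0252). Interferon-stimulated genes (9 higher and 20 lower of 49, or 9 and 21 adjusted over the list alone, camera adjusted p = 0.141, range 0.0105 to 0.557) passed without MLN8237 replicate 3 (0.0482). SUV39H1 (-0.44 ± 0.102, edgeR adjusted p = 0.00347), SUV39H2 (0.27 ± 0.0806, 0.0156) and EHMT2 (-0.33 ± 0.0994, 0.0153) passed and AURKA (0.01 ± 0.0857, 0.925) did not. EHMT2 missed the threshold in a fit of only the groups compared (0.0828) and without MLN8237 replicate 1 (0.0607) or combination replicate 1 (0.0537) or 3 (0.0514), over a range of 0.00108 to 0.0828. SUV39H2 missed it with no filter (0.13) and in a fit of only the groups compared (0.0694), over a range of 0.00178 to 0.13. In all, 10487 genes changed, 5310 higher and 5177 lower, and 2790 and 1056 of them by more than 2-fold.

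The interaction asked whether the log2 change with both compounds differs from the sum of the changes with each. Replication genes had a median interaction of -0.28 over 49 members (camera adjusted p = 1.17e-08, and adjusted p = 0.711 with an estimated correlation), with GINS2 (-0.67 ± 0.177), PCNA (-0.61 ± 0.174) and E2F1 (-0.55 ± 0.166) each at an edgeR adjusted p = 0.362. Ribosomal protein genes had -0.54 over 148 (camera adjusted p = 9.79e-14, and adjusted p = 0.866 with an estimated correlation) and metallothioneins -0.60 over 9 (adjusted p = 0.00989, and adjusted p = 0.866 with an estimated correlation), the latter lost without MLN8237 replicate 3 (0.0648, median -0.37, lowest over camera settings 0.0018). Interferon-stimulated genes had -0.17 over 49 (adjusted p = 0.00653, and adjusted p = 0.711 with an estimated correlation), lost without MLN8237 replicate 2 (0.067, median -0.09, lowest 8.12e-05), and ZNF genes 0.14 over 493 (adjusted p = 0.00236, and adjusted p = 0.866 with an estimated correlation), lost with no filter (0.0748, lowest 8.68e-05). In MLN8237 replicate 3, which stood apart from its group, ribosomal protein genes held 6.24% of counts, against 4.07% and 4.29% in its group mates. Without it the ribosomal median was -0.29. The median of metallothioneins was -0.91 without combination replicate 3, and that of ZNF genes 0.09 without MLN8237 replicate 3 or combination replicate 1. No member of these 5 lists passed, over all genes or adjusted over the list alone. Epithelial genes, with a median of -0.21 over 33 (camera adjusted p = 0.0633, range 0.0114 to 0.711), passed without vehicle replicate 2 (0.0353), chaetocin replicate 3 (0.0117), MLN8237 replicate 3 (0.0172) or combination replicate 2 (0.0115). Germline genes (0.371, range 0.00907 to 0.902) passed without chaetocin replicate 3 (0.0236) or combination replicate 2 (0.00907), and histone genes (0.361, range 0.0317 to 0.902) without combination replicate 2 (0.0317).

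For single genes in the interaction, by edgeR 0 genes passed, with 3108 at an unadjusted p under 0.05, 15 called by DESeq2 and 0 by limma-voom. The 3108 became 1908 without vehicle replicate 2, 1901 without vehicle replicate 3, 1838 without chaetocin replicate 3, 4943 without MLN8237 replicate 1 and 1322 without combination replicate 1. PRDM10 (0.83 ± 0.158), LPAR6 (1.66 ± 0.36), RYBP (0.49 ± 0.113), CTGF (-0.58 ± 0.126), EDN1 (-0.55 ± 0.119) and ADA (-0.53 ± 0.132) had the smallest p under the rule (edgeR adjusted p = 0.362 each). By DESeq2 PRDM10 had an adjusted p = 0.00912 (range over alternatives 0.00912 to 0.713), EDN1 0.0173 (0.0173 to 0.713) and LPAR6, RYBP and CTGF 0.0283 (0.0283 to 0.713). The pseudogene RP3-375P9.2, chosen after its values were seen, had the smallest edgeR adjusted p, 0.063, with 0.000857 under no filter and 1.35e-05 by DESeq2 (range 1.35e-05 to 0.451). LPAR6, CTGF, ADA, GINS2 and PCNA overlap other genes. AURKA (0.02 ± 0.121), SUV39H1 (-0.18 ± 0.143), SUV39H2 (0.09 ± 0.114), EHMT2 (-0.12 ± 0.14) and TXNRD1 (0.17 ± 0.194) had edgeR adjusted p = 0.94, 0.526, 0.685, 0.677 and 0.668.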

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

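The tests of depth, genomic DNA, gene length, swapped or wrongly labelled libraries, a weaker response and whole-library measures here were chosen only after the result was seen, as was the test of lists with no filter, and the other interaction tests of gene lists were planned.

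Reads over genes silent in vehicle were higher with chaetocin, a signal outside the comparisons. Over 14303 genes of at least 500 bases with at most 3 counts in vehicle, the mean RPKM computed from the counts was 0.0151 ± 0.00616 in the 6 chaetocin-containing libraries (SD, n = 6) and 0.00384 ± 0.000299 with MLN8237 (n = 3), above the highest MLN8237 library in 6 of 6 (two-sided exact permutation p = 0.0476, adjusted p = 0.0476 over 6 measures), vehicle being left out because it defined the genes. Genes with a count numbered 32240 ± 984 (30980 to 33443) against 28624 ± 625 (27987 to 29771) in the other 6 libraries (two-sided exact permutation p = 0.00216, adjusted p = 0.00432). Depth is argued against, since after thinning to equal totals the lowest chaetocin-containing library stayed 1290 genes above the highest other. So is evenly spread genomic DNA as the whole source. Of 3208 silent genes with a count in an MLN8237 library, 20.1 to 29.1 percentage points more were at 0 than an even density gives. At most 5 were allowed. Uneven DNA, even DNA in part, transcription running past gene ends and a biological effect of chaetocin stay open and were not tested.

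MLN8237 replicate 3 stood apart from its group, at a root mean square distance of 0.442 from its group mates on the log2 scale over 11307 expressed genes, where the largest of the other 11 libraries was 0.268. A gene length trend as the whole cause is argued against, since with each library's trend removed the distance was 0.411 against at most 0.245 elsewhere. That test was at first run over all 22831 tested genes, where the distance went from 0.691 to 0.724 against at most 0.532 elsewhere, and the expressed genes were chosen after that was seen. A swap with a chaetocin-containing library is argued against too, since it lay at 0.111 between vehicle (0) and chaetocin (1). Its deviations from its group mean correlated at 0.441 and 0.436 with those of chaetocin and combination replicates 3, and at 0.075 with those of vehicle replicate 3. Chaetocin and combination replicates 3 correlated at 0.462. A difference in culture or preparation, of this library alone or shared by the 3 treated libraries numbered 3, stays open, and no biological explanation was tested.

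Combination replicate 2 lay near the chaetocin libraries, at 0.987 on the axis from vehicle (0) to chaetocin (1), with its group mates at 1.3 and 1.32. A swap with a chaetocin library is argued against, since the highest of those lay at 1.06, below both group mates, and so is a chaetocin library under a wrong label, since mean log2 CPM of 60 mitotic genes minus that of 49 replication genes was 1.12 in combination replicate 2, 0.37 above the highest chaetocin library, where each of the 3 had 0.75. A linear gene length trend is argued against too. Over 3958 expressed genes the library lay at 0.942 with linear trends removed, below the midpoint of 1.17 between the groups. A first run over 6793 genes, seen before, gave 0.999. A weaker response of that library to MLN8237 stays open, since its 1.12 lay below the 1.23 and 1.21 of its group mates but nearer to them than to chaetocin. Its mitotic mean of 7.38 lay above both (7.31 and 7.27) and its replication mean of 6.26 between theirs (6.08 and 6.06) and the lowest chaetocin library (6.35).

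The percentage of the RPKM denominator lying outside the gene counts, which the comparisons did not use, was 3.73 ± 0.503 in the 6 chaetocin-containing libraries and 1.94 ± 0.707 in the other 6, with vehicle replicate 3 overlapping them at 3.34 (two-sided exact permutation p = 0.00433, adjusted p = 0.00649 over 6 measures). By the interaction test the change with MLN8237 differed with and without chaetocin for 5 lists, with medians of -0.28 for replication genes, -0.60 for metallothioneins, -0.17 for interferon-stimulated genes, 0.14 for ZNF genes and -0.54 for ribosomal protein genes. None of the 5 passed with an estimated correlation (adjusted p = 0.711, 0.866, 0.711, 0.866 and 0.866). The metallothionein call was lost without MLN8237 replicate 3 (0.0648, range over camera settings 0.0018 to 0.866), the interferon call without MLN8237 replicate 2 (0.067, range 8.12e-05 to 0.711) and the ZNF call with no filter (0.0748, range 8.68e-05 to 0.866). Without MLN8237 replicate 3 the medians were -0.29 for ribosomal protein genes, -0.37 for metallothioneins and 0.09 for ZNF genes, without MLN8237 replicate 2 -0.09 for interferon-stimulated genes, without combination replicate 3 -0.91 for metallothioneins, and without combination replicate 1 0.09 for ZNF genes.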

How the results depend on the processing

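The omission of the 3 treated libraries numbered 3, of MLN8237 replicate 3 where it was not compared, the length-trend offsets and both filters for gene lists were chosen after seeing the data. The other alternatives were planned. Of 2979 values of named genes under alternatives, 2899 kept their side of the threshold, 32 no longer passed and 48 newly passed. Where either value passed, 0 reversed. Requiring an absolute log2 fold change of at least 1 left 1989 genes for chaetocin, 3406 for the combination and 3846 for the combination against MLN8237, by construction. For MLN8237 against vehicle the stricter filter, which left out the low pseudogene, and the fit of only the groups compared gave 0 genes. For the combination against chaetocin no filter gave 36, DESeq2 296 and limma-voom 1, and for the interaction no filter gave 2 and DESeq2 15. The cause was not tested for these or for the changes below. Omitting a compared library gave 3704 (vehicle replicate 2) to 4705 genes for chaetocin and 0 (vehicle replicates 2 and 3) to 1 for MLN8237. It gave 6564 to 9095 with both, 0 to 573 (combination replicate 2) against chaetocin, 7659 to 10542 against MLN8237 and 0 for the interaction. Without MLN8237 replicate 3 chaetocin had 7551 and both 11045. With an estimated correlation 0 lists passed in each of the 6 comparisons. Fry, which does not compare a list with other genes, gave in its mixed form 28 lists for chaetocin, 0 for MLN8237, 29 for the combination, 29 for the combination against MLN8237 and 3 for the interaction. In its directional form it gave 1 for MLN8237, 4 for the combination against chaetocin and 0 for the interaction. Leaving out a library gave 11 to 12 lists for chaetocin, 1 (vehicle replicate 3) to 5 for MLN8237, with 3 without MLN8237 replicate 2, and 11 to 14 for the combination. It gave 5 (chaetocin replicate 2, combination replicate 3) to 12 for the combination against chaetocin, with 7 without chaetocin replicate 1, 12 to 15 against MLN8237 and 4 to 8 (combination replicate 2) for the interaction, which also had 8 without the treated libraries numbered 3. In the order of the report, no filter gave 11, 6, 13, 9, 17 and 4 lists and the stricter filter, under which 28 lists could be tested, 10, 6, 11, 8, 10 and 5, and the calls each ended stand in the report. Some lists that did not pass as reported passed with another setting, and several of them with more than 1. With the stricter filter these were ZNF genes for chaetocin (0.00918), histone genes (1.22e-05) and ductal markers (0.0177) for MLN8237, NF-kB genes for the combination (0.0277) and against MLN8237 (0.0169), Aurora kinase genes against chaetocin (0.0272) and DNA repair genes against MLN8237 (0.0403). With no filter they were immediate early genes for MLN8237 (0.0467), Polycomb genes (0.0456) and immune markers (0.0398) for the combination, cholesterol (0.0193) and interferon-stimulated genes (0.0217) against chaetocin, and NF-kB (0.0208), interferon-stimulated (0.0105) and immune genes (0.0431) against MLN8237. Without the treated libraries numbered 3 they were replication (0.0269), DNA repair (0.0201) and ZNF genes (0.02) for chaetocin, histone genes (0.0423) and endothelial markers (0.00729) for MLN8237, cholesterol genes against chaetocin (0.0239), and cholesterol (0.0375), epithelial (0.0114) and mitochondria-encoded genes (0.019) in the interaction. With length-trend offsets they were autophagy (0.049) and mitochondria-encoded genes (0.00142) for MLN8237 and epithelial (0.0366) and mitochondria-encoded genes (0.0203) in the interaction. In the interaction the mitochondria-encoded list pointed down as reported (0.689) and up in both of these settings. Passes with a library left out stand in the report. The highest values of these lists over camera settings ran from 0.378 (NF-kB genes against MLN8237) to 1 (mitochondria-encoded genes for MLN8237). The overlap between chaetocin and MLN8237 stayed at 0. RLE scaling moved the median of all genes by at most 0.02 (log2) and shared 5449 calls for chaetocin and 8550 for the combination. Low counts limit genes such as MLC1, with 6 counts in vehicle. No 2 groups compared directly had every correlation of same-numbered deviations above 0.1 (-0.153 to 0.462), so the replicate numbers were not taken to pair libraries. Chaetocin and MLN8237, not compared directly, gave 0.314, 0.119 and 0.441, and 7 of 12 libraries correlated best with their own number, a hint from the data and not the design. With the number as a block, 6798, 1, 10024, 0, 11768 and 0 genes and 11, 4, 13, 12, 13 and 6 lists passed in the order of the report. The block ended the calls of interferon-stimulated genes with MLN8237 (0.065) and endothelial markers against MLN8237 (0.0629). It gave calls to cholesterol genes against chaetocin (0.0305) and epithelial genes in the interaction (0.0431), and changed no other list call.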

Other observations

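The tests of gene type, abundance and library percentages here were chosen only after the result was seen, and those of single genes and of splits were planned.

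With chaetocin 276 of 1234 long intergenic non-coding RNAs rose and 42 fell, and with the combination 427 and 82. Of 14812 protein-coding genes these were 1972 and 2351, and 3044 and 3473. Such RNAs held 0.422% ± 0.0353 of counts in the 6 chaetocin-containing libraries and 0.328% ± 0.0187 in the other 6, without overlap (n = 6, two-sided exact permutation p = 0.00216, adjusted p = 0.00432 over 6 measures). Of 6476 genes with a mean under 1 CPM 969 rose and 178 fell with chaetocin, and of 16355 others 1905 and 2539. Antisense genes gave 250 and 162 and processed pseudogenes 80 and 20. Type was not separated from abundance. Mitochondria-encoded genes held 2.91% ± 0.34 and 2.41% ± 0.225 of counts in the same libraries, which overlapped (lowest 2.5 with chaetocin, highest 2.66 without; two-sided exact permutation p = 0.00649, adjusted p = 0.00779).

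Further single genes moved with chaetocin or the combination. NDRG1, a hypoxia-responsive gene, rose from 5.17 ± 0.571 to 20.4 ± 4.65 CPM with chaetocin, the histone demethylase gene KDM6B from 9.78 ± 1.97 to 24.7 ± 3.39 CPM, and SCG2, a gene of neuroendocrine granules, from 0.942 ± 0.147 to 3.73 ± 0.113 CPM (edgeR adjusted p = 9.07e-05, 0.00137 and 9.44e-05). BIRC3, an inhibitor of apoptosis, fell by 1.10 ± 0.128 on the log2 scale from 284 ± 10.8 CPM, and the ductal keratin gene KRT19 fell from 418 ± 19.8 to 192 ± 22.2 CPM (edgeR adjusted p = 8.32e-05 and 0.000769). BRCA2, which overlaps IFIT1P1, rose from 24.6 ± 3.96 to 52.1 ± 13.4 CPM with the combination (edgeR adjusted p = 0.000278), and TNFRSF10D from 6.74 ± 0.14 to 46.2 ± 12.2 CPM (edgeR adjusted p = 1.71e-06).

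For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Between chaetocin and vehicle the real split gave 5591 genes and the highest other 1, with 1 split as large. Between MLN8237 and vehicle these were 1 and 0, between the combination and vehicle 8780 and 0, and between the combination and MLN8237 10487 and 0, each with 1 split as large. Between the combination and chaetocin all 10 splits gave 0, and for the interaction all 50, the real one included. Against a real 0 every split is as large, so chance was neither tested nor excluded there.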
